A study of Homo sapiens with 10 samples.

How the data were processed

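Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the corepressors RCOR1, RCOR2 and RCOR3 and the histone demethylase LSD1 (gene symbol KDM1A) in Kelly cells, an adrenergic neuroblastoma line with amplified MYCN. The 10 libraries form 5 groups of 2, per the labels. RCOR2 was pulled down through a FLAG tag from cells given 2 µg/mL doxycycline (48 h) and, as background, from untreated cells of the same kind with the same antibody. RCOR1 and RCOR3 were pulled down with their own antibodies from untreated cells. LSD1 came from a different Kelly derivative, which carries a doxycycline-driven shRNA against RUNX1T1 and was not treated, per the series description.

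Reads were aligned with BWA 0.7.17 to GRCh38 and peaks were called with MACS2, per the submitters' processing notes, which also name deepTools and give no version for either of these tools. Each deposited list holds the peaks of a single library. Its fold enrichment per peak is a ratio over local background as the authors' peak caller wrote it. Its second value is the −log10 of the q-value that the authors' peak caller gave each peak, and its smallest values lie at a q-value of 0.05. The control library, the handling of duplicates and any later filter are not given in the sources used here. A pair of further deposited lists for the whole series, named RCOR2-high and RCOR2-low, holds region positions with no values. How these classes were defined is not given in the sources used here. Peak names within every list name the protein, and for FLAG the treatment, that the label gives. Those of RCOR1 replicate 2, RCOR3 replicate 2 and the FLAG lists carry other replicate names than the labels, and replicates are numbered here per the labels. No read counts were used, so the read depth per library is unknown and only the number of peaks can be given. Intervals (Wilson, 95%) and tests over regions or genes cover counting error only. The labels do not say that the replicates are separate cultures, so p-values across libraries may measure technical spread.

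Peaks on chromosomes 1 to 22 and X were used. The consensus regions of a group are the merged peaks of its 2 libraries that hold at least 1 peak of each, with an overlap of at least 1 bp. Similarity of libraries was the base-pair Jaccard index. The only annotation used was a table of RefSeq genes on GRCh38 without strand. Start and finish of transcription could therefore not be told apart, and the window of 2 kb around either end of a protein-coding gene, called a gene end here, takes the place of the promoter. The table holds 19974 protein-coding genes.

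Similarity and gene-end shares of the 8 libraries of the 4 proteins were tested over the 105 distinct assignments of the libraries to groups (exact permutation tests). Overlap of regions was tested against 1000 shuffles within chromosomes (one-sided), for which stretches of at least 1 Mb without any gene or peak were left out in place of assembly gaps. The smallest p these shuffles can give is 0.000999. RCOR2-high and RCOR2-low regions and gene lists were compared with Fisher's exact test (two-sided) and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. The log2 odds ratio of a list includes a continuity correction. With 2 libraries against 2, an exact two-sided test cannot go below 0.333.

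The 19 gene lists cover adrenergic core regulators, mesenchymal-state genes, the LSD1-CoREST complex, REST target neuronal genes, noradrenergic transmitter genes, Schwann and glial markers, MYC targets, cytosolic ribosomal proteins, replication-dependent histones, cell cycle, oxidative phosphorylation, cholesterol synthesis, p53 targets, antigen presentation and interferon, immediate early genes, HOX genes, splicing factors, and liver and keratinocyte genes as other tissues. Of their 523 genes 522 were found by symbol. Genes were named by a rule: all members of the adrenergic and LSD1-CoREST lists with a region, up to 4 members of every other list with a call, taken by the lower of the 2 libraries' percentile ranks of the authors' score, and the 10 strongest regions per protein and of RCOR2-high by the same rank. Not every gene that the rule takes is printed. The groups, comparisons, tests, lists, naming rule and most alternative settings were fixed before the data were examined.

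The alternatives included equal numbers of top peaks per library (13644), peaks set to 500 bp, 50% reciprocal overlap, peaks of either library, the peaks above each library's median score, gene-end windows of 500 bp, the nearest gene end within 100 kb, other backgrounds, removal of regions with an uninduced FLAG peak, removal of 2 Mb either side of MYCN, and leaving out each replicate. Sequence motifs and the CpG-rich background need a genome sequence and were not analysed here. The tests were tried on simulated data. With 5% of 35875 RCOR2 regions placed on LSD1 regions, the share above expectation came back as 4.98%, and 1 of 20 runs without placement fell under the threshold. Randomly drawn gene lists were called in 0.0526% of 1900 tests over 19974 genes for RCOR1. Simulated libraries without a protein effect passed the exact permutation test in 5.5% of 200 runs for similarity and in 7.0% for the gene-end share (8 libraries). Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.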

Results

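The data are peak lists from Kelly neuroblastoma cells for LSD1, RCOR1, RCOR3 and FLAG-tagged RCOR2, with 2 libraries per protein and 2 FLAG libraries from uninduced cells. The peaks used per library numbered 49250 and 18297 for RCOR1, 75643 and 59726 for induced RCOR2, 13644 and 27786 for RCOR3, 19392 and 19667 for LSD1, and 10253 and 14958 for the uninduced FLAG control. Peaks shared by both libraries gave 13516 consensus regions for RCOR1, 35875 for RCOR2, 7179 for RCOR3, 12695 for LSD1 and 3151 for the uninduced control. Because tagged RCOR2 was expressed from a transgene and LSD1 was measured in another Kelly derivative, differences between these proteins also include differences between cells and antibodies.

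Before the libraries were pooled, it was asked whether libraries of the same protein resembled each other most. LSD1 and induced RCOR2 gave the most similar pairs, with Jaccard indices of 0.490 and 0.438. The pair of RCOR3 libraries reached 0.201 and the pair of RCOR1 libraries 0.173. RCOR1 replicate 2 was closer to RCOR3 replicates 1 and 2 (0.271 and 0.295) than to RCOR1 replicate 1, and RCOR1 replicate 1 was closest to LSD1 replicate 1 (0.218). Over all 8 libraries, the mean index was 0.325 within proteins and 0.140 between proteins, a difference of 0.186 (one-sided exact permutation p = 0.0286). The difference lost its call without either induced RCOR2 library (0.128 and 0.132, exact p = 0.0571 for both) and without LSD1 replicate 1 or 2 (0.129 and 0.130, exact p = 0.0952 and 0.0857). It also lost it with a replicate block, in which only libraries of different replicate numbers were compared (0.188, exact permutation p = 0.0833, smallest possible 0.0417).

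**Figure D1:**
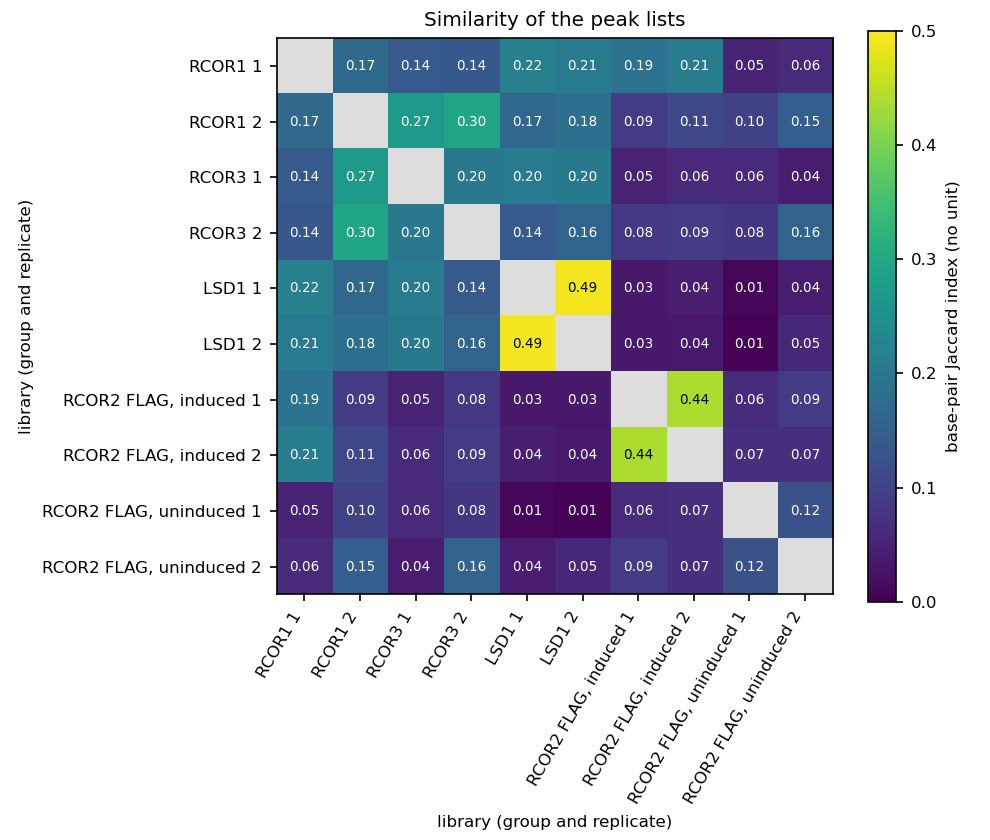
Base-pair Jaccard index (no unit, colour and number) of each pair of the 10 peak lists, with libraries named by group and replicate on both axes. The LSD1 pair (0.490) and the induced RCOR2 pair (0.438) stand out, while RCOR1 replicate 2 lies closer to both RCOR3 libraries than to RCOR1 replicate 1.

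The uninduced FLAG libraries show which peaks were found without doxycycline. Induced cells had a mean of 67684 peaks ± 11255 (SD, n = 2) and uninduced cells 12606 ± 3327 (SD, n = 2), a 5.37-fold difference. An uninduced peak lay in 26.1% of the 35875 RCOR2 regions (95% interval 25.7 to 26.6%), in 17.8% for uninduced replicate 1 and in 15.2% for replicate 2. Seen from the control, 69.6% and 39.3% of the peaks of the uninduced replicates 1 and 2 lay in RCOR2 regions. The share of 26.1% fell to 6.47% when 50% reciprocal overlap was asked for and to 16.9% without induced replicate 1. An uninduced peak also lay in 34.0% of the RCOR1, 27.8% of the RCOR3 and 7.15% of the LSD1 regions. Those with and without RCOR2 were not counted apart, so these shares cannot show whether the overlap was particular to RCOR2.

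RCOR2 regions coincided with each of the other proteins far more often than shuffled regions did. RCOR1 regions overlapped 25.9% of RCOR2 regions, 27.5 times the 0.939% of shuffled regions. RCOR3 overlapped 10.9% (29.9 times) and LSD1 7.12% (11.5 times), each with permutation p = 0.000999, the smallest the 1000 shuffles can give. These shares depended on how overlap was counted. Without replicate 1 and without replicate 2 of the other protein, they were 28.7% and 47.6% for RCOR1, 25.1% and 17.9% for RCOR3 and 8.03% and 9.68% for LSD1. In the same order without the induced replicates, they were 18.5% and 14.2% for RCOR1, 7.65% and 6.09% for RCOR3 and 6.47% and 5.00% for LSD1. With 50% reciprocal overlap they were 13.6% for RCOR1, 4.55% for RCOR3 and 3.40% for LSD1, with peaks above the median score 18.7%, 5.85% and 3.88%, with peaks of either library 26.7%, 17.1% and 7.86%, and among RCOR2 regions without an uninduced peak 16.8%, 7.27% and 6.13%. At gene ends 32.9% of RCOR2 regions overlapped RCOR1 and 2.56% LSD1, against 20.5% and 10.6% elsewhere. With the shuffle restricted to keep gene-end regions at gene ends, the enrichments were 7.42 times for RCOR1, 11.1 times for RCOR3 and 10.9 times for LSD1. Without single replicates the enrichment ranged from 18.9 to 36.5 times for RCOR1, from 22.7 to 30.4 for RCOR3 and from 9.62 to 14.0 for LSD1, and with 50% reciprocal overlap it was 63.6, 74.4 and 26.8 times.

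LSD1 sites overlapped RCOR1 and RCOR3 more often than RCOR2. Of the 12695 LSD1 regions, 41.3% overlapped RCOR1, 30.7% RCOR3 and 19.3% RCOR2, although RCOR2 had the longest list. In the other direction, 55.3% of RCOR3 regions, 36.9% of RCOR1 regions and 7.12% of RCOR2 regions overlapped LSD1. With equal numbers of top peaks per library the RCOR2 share of LSD1 regions was 3.15%, against 39.5% for RCOR1 and 29.6% for RCOR3. Counted per library, the means were 61.9% ± 30.5 for RCOR1, 42.6% ± 3.10 for RCOR3 and 27.6% ± 0.501 for RCOR2 (SD, n = 2 each). The exact two-sided p was 0.333, the smallest possible, for RCOR2 against either of RCOR1 and RCOR3, and 1 for RCOR1 against RCOR3. The RCOR1 share depends on the library, at 83.5% for replicate 1 and 40.4% for replicate 2.

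The 46991 merged regions of the 4 proteins fell into classes with different positions. RCOR2 alone held 25862, of which 39.1% lay at gene ends, and RCOR2 with RCOR1 held 4783, of which 71.0% did. LSD1 alone held 6623 with 3.49% at gene ends, and RCOR1, RCOR3 and LSD1 without RCOR2 held 1824 with 3.67%. All 4 proteins met at 1516 regions, 14.5% of them at gene ends. Among RCOR1 regions, a split chosen after the data were seen gave LSD1 in 21.5% of those with RCOR2 and in 68.2% of those without. That difference held at gene ends (6.5% against 37.2%) and away from them (41.7% against 70.7%).

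The mean share of peaks at gene ends was lowest for LSD1, close to that of random positions. The gene-end share of peaks was 7.31% ± 2.89 for LSD1, 24.2% ± 7.78 for RCOR3, 29.995% ± 3.92 for induced RCOR2 and 35.4% ± 6.10 for RCOR1 (SD, n = 2 each). It was 30.7% ± 17.6 (SD, n = 2) in the uninduced control and 5.66% for random positions. The 4 proteins did not pass the test over all peaks (F = 9.77, exact permutation p = 0.0571). They did with equal numbers of top peaks (F = 28.6, exact p = 0.00952), where induced RCOR2 reached 61.6% ± 5.49 (SD, n = 2), and without RCOR3 replicate 1 (F = 15.03, exact p = 0.0286).

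The submitters' RCOR2-high and RCOR2-low lists were compared for the other proteins, although how the classes were defined is not given. Neither induced library had a peak in 46.0% of RCOR2-low regions, so the comparison is not only one of RCOR2 binding strength. RCOR2-high regions lay mostly at gene ends and seldom held LSD1. Of 6673 RCOR2-high regions 80.1% were at gene ends, against 21.7% of 24637 RCOR2-low regions (odds ratio 14.4). LSD1 regions were found in 4.09% of RCOR2-high and 40.2% of RCOR2-low regions (odds ratio 0.0635). Both differences had an adjusted exact Fisher p of at most 1.33e-300, the floor of the calculation. The LSD1 libraries gave 8.89% and 5.02% in RCOR2-high and 47.3% and 46.6% in RCOR2-low regions.

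The LSD1 difference was found at gene ends (3.18% against 10.5%) and away from them (7.74% against 48.4%). Over the called induced RCOR2 peaks of the 2 libraries, median fold enrichment was 18.6 and 38.2 in RCOR2-high and 7.01 and 6.84 in RCOR2-low regions. Regions without a called peak have no value and do not enter these medians. RCOR1 was found in 60.3% of RCOR2-high and 31.2% of RCOR2-low regions, which turned to 91.0% and 91.8% without RCOR1 replicate 2. RCOR3 was found in 20.9% and 19.4% (adjusted exact Fisher p = 0.00761), a difference of 1.47 points that rested on the setting. It was −1.59 points with regions set to 500 bp, −6.83 points without uninduced peaks and −6.13 points among regions that hold an RCOR2 consensus region, but 22.9 points without RCOR3 replicate 1 and 19.4 points with peaks of either library. It lost its call without RCOR3 replicate 2 (1.34 points, exact p = 0.168) and away from gene ends (2.67 points, exact p = 0.0910).

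The make-up of these lists bears on their reading. Of the listed regions 97.2% had the exact bounds of a merged region of the RCOR1 and induced RCOR2 peaks, so their RCOR1 share follows in part from how they were made. Both induced libraries had a peak in 99.9% of RCOR2-high and 33.1% of RCOR2-low regions, and neither had a peak in 46.0% of RCOR2-low regions. Among regions that hold an RCOR2 consensus region, LSD1 was found in 4.10% of RCOR2-high and 23.03% of RCOR2-low regions. Uninduced FLAG peaks were found in 40.3% ± 17.5 of RCOR2-high and 4.45% ± 0.0947 of RCOR2-low regions (SD, n = 2).

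**Figure D2:**
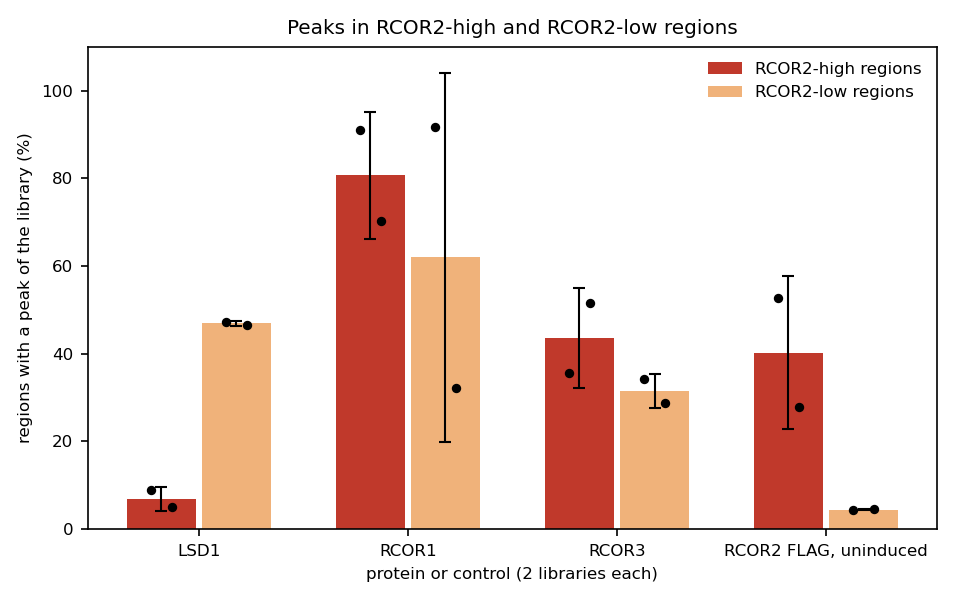
Percent of RCOR2-high and RCOR2-low regions that hold a peak of each LSD1, RCOR1, RCOR3 or uninduced FLAG library, as points per library (replicate 1 left, replicate 2 right) with bars at the mean and error bars of 1 SD (n = 2). Both LSD1 libraries lie below 10% in RCOR2-high and above 46% in RCOR2-low regions, while the uninduced control shows the opposite order.

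RCOR2 had a region at an end of 14138 of the 19974 genes (70.8%), so most gene lists were nearly filled. All 30 MYC targets and all 30 splicing factors had an RCOR2 region, as did 61 of 66 cytosolic ribosomal protein genes, 29 of 30 cell cycle genes, 31 of 32 oxidative phosphorylation genes, 19 of 20 p53 targets and 37 of 39 HOX genes. Strong examples were PTMA (fold enrichment 36.5 and 85.6 in replicates 1 and 2), WDR43, a ribosome biogenesis factor (38.0 and 54.0), HNRNPU (34.1 and 72.3), RPL6 (27.1 and 69.1), MDM2, the negative regulator of p53 (34.3 and 88.8), and BIRC5 (29.3 and 52.5). HOXC4, HOXC5 and HOXC6 shared a peak at 78.6 and 62.7. Genes of other tissues and immune genes were bound less often than the rest, with 4 of 25 liver genes, 3 of 24 keratinocyte genes and 4 of 22 antigen presentation and interferon genes. These 10 lists were called (adjusted p from 1.7e-07 to 0.040).

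None of the 10 RCOR2 list calls was kept among genes bound by at least 1 of the proteins, nearly all of which have RCOR2. There the log2 odds ratio lay between −1.59 and 0.26 for the 7 lists called higher. All MYC targets, splicing factors, cell cycle genes and p53 targets left there had RCOR2, against 98.4% of other genes. The negative values of these lists come from the continuity correction. Of the 3 lists called lower, only 5 antigen presentation and interferon, 5 liver and 3 keratinocyte genes were left, of which 4, 4 and 3 had RCOR2, too few for a call. Their log2 odds ratios were −4.40 (SE 1.36), −4.40 (SE 1.36) and −3.17 (SE 2.18). The last of these comes from the continuity correction, since all 3 keratinocyte genes had RCOR2. Without regions that hold an uninduced peak, the log2 odds ratio went from 4.66 to −0.12 for MYC targets, from 4.66 to −0.70 for splicing factors, from 2.21 to −0.02 for ribosomal proteins, from 3.12 to −0.47 for oxidative phosphorylation and from 2.43 to −0.21 for p53 targets, and the cell cycle list lost its call (0.44, adjusted exact p = 0.681). In that setting the other 4 lists kept their calls, with 3.05 for HOX genes (adjusted exact p = 3.0e-06) and −5.43 for antigen presentation and interferon (1.0e-05). For liver and keratinocyte genes it was −2.20 (0.00564) and −2.56 (0.00198). The size of the −5.43 is set by the continuity correction and does not measure a stronger depletion. Leaving out uninduced peaks also removes strong RCOR2 sites, since they lay in 61.8% of RCOR2-high and 26.1% of all RCOR2 regions. The calls lost in this setting therefore cannot tell background from RCOR2 binding. With 500 bp windows the HOX call (0.54, adjusted exact p = 0.495) and the p53 call (1.37, adjusted exact p = 0.179) were lost, and the p53 call was lost without induced replicate 2 as well (1.28, adjusted exact p = 0.317). By nearest gene end the log2 odds ratio was 1.48 for MYC targets and for splicing factors, 0.72 for cell cycle and −0.19 for oxidative phosphorylation, without calls (adjusted exact p from 0.111 to 0.913). The p53 list was not called there either (adjusted exact p = 0.0799), but its log2 odds ratio was about as large (2.43 with an SE of 1.22 at gene ends, 2.21 with an SE of 1.22 by nearest gene end), with 19 of 20 members in both settings against 70.8% and 73.8% of other genes. With equal numbers of top peaks the log2 odds ratio was −0.16 for ribosomal proteins, 0.17 for cell cycle, 0.19 for oxidative phosphorylation and −1.14 for HOX genes, without calls (adjusted exact p from 0.0990 to 0.982).

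RCOR1 had a region at an end of 30.5% of genes and was found more often at splicing factors (24 of 30), p53 targets (16 of 20), histones (23 of 32), oxidative phosphorylation genes (20 of 32), MYC targets (16 of 30) and cell cycle genes (16 of 30), with adjusted p from 5.8e-07 to 0.0295. Examples were HNRNPH1 (9.73 and 7.88), GADD45A, a growth arrest gene (11.6 and 6.30), NDUFA9 (10.4 and 7.27), CDK4 (9.47 and 6.62) and RRM2 (10.7 and 6.49). Keratinocyte genes were found less often (1 of 24, KRT17). RCOR3, with 10.6% of genes, was found more often at histones (13 of 32), MYC targets (11 of 30), oxidative phosphorylation genes (11 of 32), p53 targets (7 of 20), splicing factors (9 of 30), ribosomal proteins (14 of 66) and adrenergic regulators (7 of 22), with adjusted p from 9.5e-05 to 0.040. Examples were H4C5 (7.10 and 7.39), RPS3A (8.40 and 7.46), SESN1 (7.43 and 6.11) and HNRNPD (6.14 and 6.72). The RCOR1 cell cycle call was lost without RCOR1 replicate 1 (log2 odds ratio 1.38 before and 1.12 after, SE 0.52 for both, adjusted exact p = 0.0805) and the RCOR3 ribosomal call without RCOR3 replicate 1 (1.23 with an SE of 0.43 before, 0.82 with an SE of 0.36 after, adjusted exact p = 0.0737). When the regions of each protein that hold an uninduced FLAG peak were left out, the log2 odds ratio of RCOR1 went from 3.11 to 0.31 at splicing factors, from 1.91 to 0.20 at oxidative phosphorylation genes and from 1.38 to 0.31 at MYC targets (adjusted exact p = 1 for each). That of RCOR3 went from 1.91 to −0.02 at splicing factors (adjusted exact p = 1), from 1.23 (SE 0.43) to 0.80 (SE 0.64) at ribosomal proteins (0.605) and from 2.32 (SE 0.54, 11 of 30 members) to 1.73 (SE 0.74, 4 of 30) at MYC targets (0.1798). Other calls ended with fewer bound members while the log2 odds ratio changed by less than its SE. For RCOR1 it was 1.38 (SE 0.52, 16 of 30 members) before and 1.35 (SE 0.56, 9 of 30) after at cell cycle genes (adjusted exact p = 0.138), and −2.78 (SE 1.22, 1 of 24) and −3.09 (SE 2.06, 0 of 24) at keratinocyte genes (0.144). For RCOR3 it was 2.18 (SE 0.53, 11 of 32) and 1.96 (SE 0.68, 5 of 32) at oxidative phosphorylation genes (0.0883) and 2.23 (SE 0.66, 7 of 20) and 1.96 (SE 0.85, 3 of 20) at p53 targets (0.218). Histones for RCOR1 and RCOR3 (3.25 and 3.77, adjusted exact p = 3.1e-08 for both), p53 targets for RCOR1 (1.97, 0.0375) and adrenergic regulators for RCOR3 (2.62, 0.0284) kept their calls. Of the calls in this paragraph, that of RCOR1 at p53 targets held under every alternative run, and the others were lost under at least 1. By nearest gene end the histone log2 odds ratio went from 2.50 to 0.45 for RCOR1 (adjusted exact p = 0.541) and from 2.56 to 1.28 for RCOR3 (0.0788). With equal numbers of top peaks it was 0.64 for RCOR1 at histones (0.577). In that setting the RCOR3 value at oxidative phosphorylation genes was 0.43 (SE 0.95, 2 of 32, adjusted exact p = 0.867).

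LSD1 had a region at an end of 4.17% of genes, and its called lists were histones (15 of 32, adjusted exact p = 3.9e-11) and noradrenergic transmitter genes (4 of 16, adjusted exact p = 0.0132). The histone genes included H1-2 (10.4 and 14.7) and H4C5 (9.56 and 11.8), and because these genes are clustered the 15 members shared 13 regions. The transmitter genes were CYB561 (6.71 and 8.77), DBH, which makes noradrenaline (3.90 and 5.37), SLC6A2, the noradrenaline transporter (6.34 and 5.96), and SLC18A1, a vesicular monoamine transporter (4.98 and 5.17). CYB561, DBH and SLC6A2 also had RCOR1, RCOR2 and RCOR3 regions. At the ends of all noradrenergic genes, an uninduced FLAG peak lay in 8 of 9 RCOR3 and 5 of 10 RCOR1 regions. It lay in 8 of 27 RCOR2 and 3 of 7 LSD1 regions. For the noradrenergic list the log2 odds ratio was 3.06 (SE 0.79). Without LSD1 replicate 2 it was 1.71 (SE 0.79, adjusted exact p = 0.128), with the same number of members but 9.94% in place of 4.15% of other genes bound. Without regions that hold an uninduced peak it was about as large, at 2.80 (SE 0.87, adjusted exact p = 0.0883), with 3 of 16 members. The noradrenergic call was also lost with peaks of either library (1.52, SE 0.79, adjusted exact p = 0.149), where 11.1% of other genes were bound. Among genes bound by at least 1 protein it was lost as well (2.55, SE 0.79, adjusted exact p = 0.0982). The histone call was lost by nearest gene end (4.37 with an SE of 0.51 before, 1.09 with an SE of 0.53 after, adjusted exact p = 0.126).

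The adrenergic core regulators, the transcription factors of this neuroblastoma state, showed RCOR2 at the ends of 20 of 22 genes (adjusted exact p = 0.0848), RCOR1 at 10 (0.263), RCOR3 at 7 (0.0206) and LSD1 at 2 (0.354). RCOR2 fold enrichment was high at TBX2 (53.1 and 79.2), PHOX2A (30.3 and 53.2), SOX11 (27.7 and 52.1), KLF13 (21.6 and 51.6), ZNF536 (18.3 and 50.5), TBX3 (18.8 and 37.7), GATA2 (30.7 and 29.2), HAND1 (13.8 and 23.7) and ISL1 (23.2 and 22.3). It was lower at DACH1, LMO1, INSM1, HAND2, TFAP2B, GATA3, MYCN and SIX3 (lower replicate from 5.36 to 11.9). The genes with RCOR1 included DACH1, HAND1, HAND2, ISL1, MYCN, PHOX2A, TBX2 and TBX3. Those with RCOR3 included HAND1, ISL1, MYCN, PHOX2A, TBX2 and TBX3. MYCN is amplified in these cells, and its surroundings held an excess of peaks in every group, the uninduced control included (13.8 times). No gene-list setting left MYCN out. Uninduced fold enrichment at TBX2 was 5.62 and 6.16 and at PHOX2A 6.61 and 5.19. With 500 bp windows RCOR3 was at 5 of the 22 genes and its call ended (adjusted exact p = 0.0847), with a log2 odds ratio of 1.77 (SE 0.71) after 2.04 (SE 0.64).

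LSD1 was at an end of few adrenergic regulators, TFAP2B among them (6.62 and 5.10), but near many more. When each region was given to the nearest gene end within 100 kb, LSD1 had a region for 16 of the 22 adrenergic regulators, against 20.04% of other genes (adjusted exact p = 3.8e-06). The counts were 18 for RCOR1, 15 for RCOR3 and 22 for RCOR2 (adjusted exact p = 0.000163, 5.0e-06 and 0.0120). Noradrenergic transmitter genes behaved alike, with 13 of 16 for RCOR1, 11 for RCOR3 and 11 for LSD1 (adjusted exact p = 0.00224, 0.000128 and 0.000287). Combinations of list and protein without a call at gene ends were called here too. Among them were mesenchymal-state genes for RCOR2 (30 of 31, adjusted exact p = 0.00949) and immediate early genes for RCOR3 (9 of 18, 0.0111). REST targets were called for RCOR1 and RCOR3 (0.0354 and 0.0403) and p53 targets for LSD1 (9 of 20, 0.0326). LSD1-CoREST genes were called for RCOR1, RCOR2 and LSD1 (0.0354, 0.0240 and 0.0438). Adrenergic regulators lie in roomier surroundings than other genes (a median of 148 kb of nearest sequence against 57.1 kb). Random lists matched on this length, a test added after the data were seen, held a mean of 6.91 ± 2.10 genes (SD, 10000 lists) with LSD1 instead of 16 (permutation p = 0.0002). Over both lists and the 4 proteins, these matched tests gave unadjusted permutation p from 1e-04, the smallest possible, to 0.0427, the latter for RCOR2 at noradrenergic genes. No other list was put to the matched test, so it cannot show whether nearness of regions is particular to these lists.

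**Figure D3:**
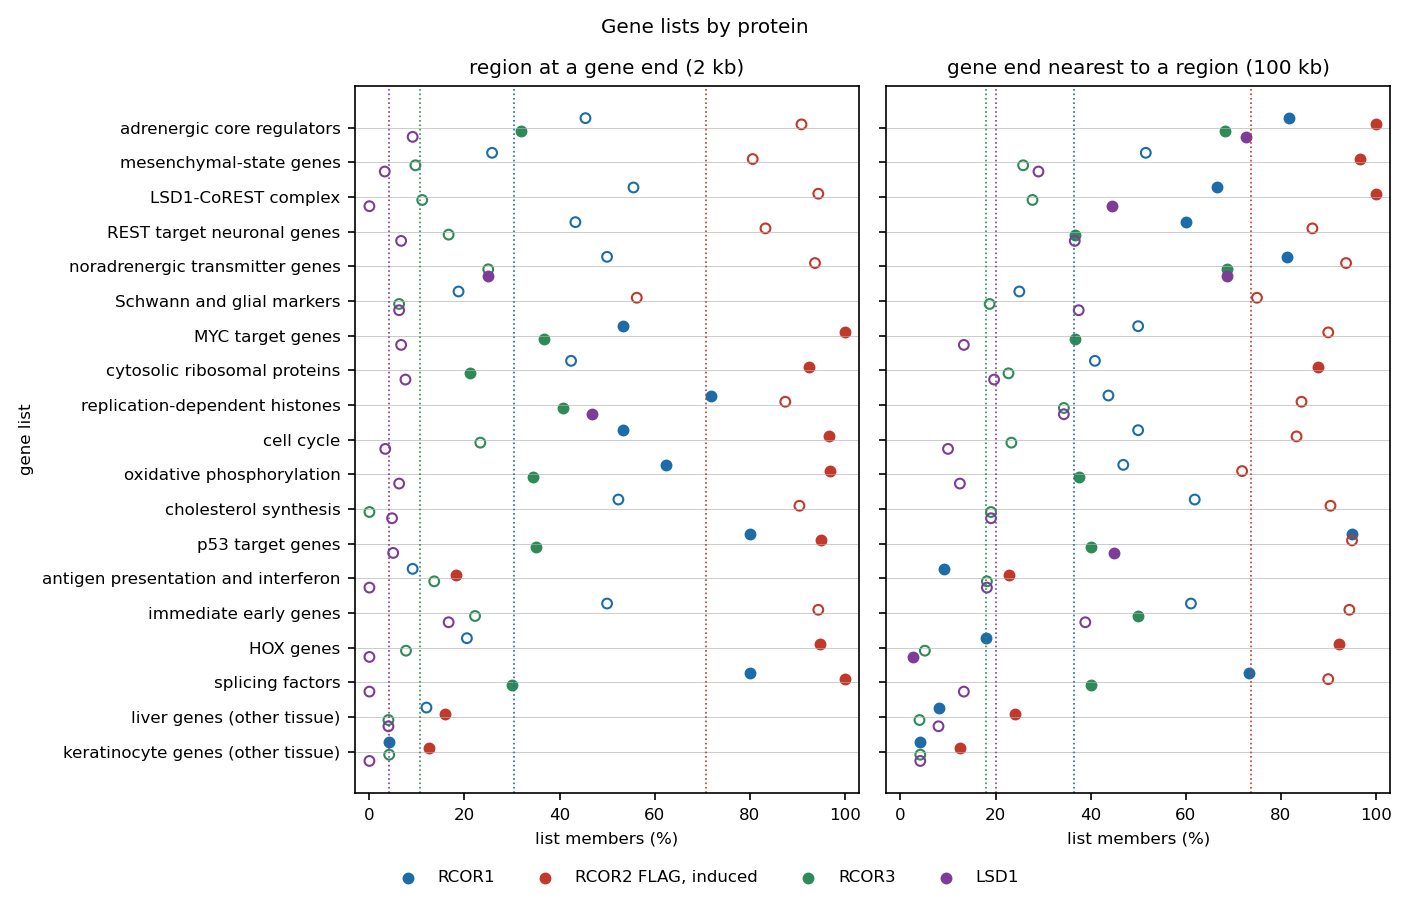
Percent of the members of each gene list with a region at a gene end (left) or as the gene end nearest to a region within 100 kb (right), by protein, with filled points for an adjusted p under 0.05 and dotted lines at the share of the genes outside a list. Adrenergic and noradrenergic lists rise for RCOR1, RCOR3 and LSD1 when distant regions are included (16 of 22 adrenergic regulators for LSD1).

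Genes of the LSD1-CoREST complex itself had RCOR2 at their ends in 17 of 18 cases (adjusted exact p = 0.0848). Fold enrichment was highest at the RCOR3 gene (78.6 and 96.5), and among the others were HDAC2 (33.5 and 57.6), RUNX1T1 (41.5 and 35.6), CTBP2 (30.4 and 33.5), KDM1A (24.9 and 74.4) and HDAC1 (23.7 and 55.3). The RCOR2 gene reached 60.9 and 86.7, with 6.22 and 5.66 in uninduced cells, and a transgene can add reads there. The 17 also included RCOR1, ZMYM2, ZMYM3, CBFA2T2, HMG20B, PHF21A, CTBP1, GSE1 and CBFA2T3. RCOR1 protein was at 10 of the genes (RCOR2, RCOR3, RUNX1T1, KDM1A, HDAC1, PHF21A, HMG20B, CTBP2, ZMYM2 and CBFA2T2), RCOR3 protein at RCOR3 and CBFA2T2, and LSD1 at none (adjusted exact p = 0.0848, 1 and 1).

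Other lists gave no call at gene ends. In the order RCOR1, RCOR2, RCOR3 and LSD1, members with a region numbered 8, 25, 3 and 1 of 31 mesenchymal-state genes, 13, 25, 5 and 2 of 30 REST targets, 3, 9, 1 and 1 of 16 Schwann and glial markers, 11, 19, 0 and 1 of 21 cholesterol synthesis genes and 9, 17, 4 and 3 of 18 immediate early genes. RCOR2 was not called against another protein for any list (0 of 57 Fisher tests, 2 at an unadjusted p under 0.05). Of the genes outside a list that had only 1 of the 2 proteins compared, 98.4 to 99.7% had RCOR2, so with all peaks this test could hardly call a list higher for RCOR2. With equal numbers of top peaks 5 tests were called, and without RCOR1 replicate 2 there was 1.

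Among the 10460 genes with an RCOR2-high or RCOR2-low region at an end, 2 lists differed. None of 29 histone genes had an RCOR2-high region, against 60.5% of other genes (adjusted exact p = 4.2e-11), and 17 of 57 ribosomal protein genes did (29.8%, adjusted exact p = 3.8e-05). By the nearest gene end 4 lists differed.

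The strongest regions of RCOR2 seldom held LSD1 but were mostly shared with RCOR1 and RCOR3. Of the 10 strongest RCOR2 regions 1 held LSD1, 9 held RCOR1 and 7 held RCOR3, and 0 of the 10 strongest RCOR2-high regions held LSD1. LSD1 was in 10 of the strongest RCOR1 and 8 of the strongest RCOR3 regions. RCOR2 was in 10 of the strongest RCOR1, 10 of the strongest RCOR3 and 8 of the strongest LSD1 regions. The strongest RCOR2 regions included the end of RCOR3, the end of PUM2, an RNA-binding repressor of translation (68.2 and 102), and a site nearest to ADAMTS17 (chromosome 15 from 99926195 to 99928731, 143 and 104). The strongest LSD1 region lay within AGBL4, 72640 bp from the nearest gene end, that of BEND5 (54.9 and 77.2). Other strong LSD1 regions lay within LIX1, 17166 bp from its nearest end (52.2 and 78.5), and 398323 bp from an end of PDE3A (43.2 and 71.5). RCOR1 was strong at the site within AGBL4 (nearest gene end BEND5, 45.5 and 23.6), at that nearest to PDE3A (47.3 and 26.8) and within BCAS3 (39.6 and 23.6). An uninduced FLAG peak lay in 10 of the 10 strongest RCOR2, 10 of the RCOR3, 8 of the RCOR1 and 4 of the LSD1 regions. Several strong RCOR1 and RCOR3 regions lay at chromosome tips, such as chromosome 5 from 9952 to 11857. The RCOR3 regions of rank 1 to 7 lay near the tips of chromosomes 5, 12, 18, X, 10, 13 and 22. All of these held LSD1 and an uninduced FLAG peak, so the sharing of strong RCOR3 regions with LSD1 rests mostly on them. RCOR1 ranks 1, 2, 6, 7 and 8 were the same sites. The RCOR2 regions of rank 2, 4, 6, 7 and 8 overlapped an snRNA gene, tRNA genes or a pseudogene (WASH9P, CROCCP2 or WASH8P).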

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

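All tests of explanations in this part, their thresholds and the split by RCOR3 replicate were chosen after the results were seen. The differences between proteins in the next paragraph were not tested, and stand here because every library of 1 group moved against every library of the other.

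Between RCOR2-high and RCOR2-low regions, LSD1 and RCOR3 differed by −52.1 percentage points and LSD1 and the uninduced control by −75.8 points. Between merged regions at gene ends and elsewhere, LSD1 differed from RCOR1 by −42.9 points, from induced RCOR2 by −60.4 points and from the uninduced control by −42.3 points. The merged regions of this second contrast are mostly RCOR2-only, so the longest list shapes it.

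LSD1 was scarce in RCOR2-high regions in both LSD1 libraries. Gene-end position as the whole cause is argued against, since the difference away from gene ends was −40.7 points. Sites without RCOR2 in the low list are argued against as the whole cause too, since the difference was −18.9 points among regions that hold an RCOR2 consensus region. It was −36.1 points over all regions, so such sites may account for part of it. Away from gene ends the same restriction took it from −40.7 to −29.0 points. LSD1 was measured in another Kelly derivative without induced RCOR2, with 0 LSD1 libraries from induced cells, so this cannot be told apart from a property of the sites. That strong RCOR2 sites bind little LSD1 therefore stays a hypothesis that LSD1 libraries from induced cells could test.

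RCOR1 replicate 2 resembled the RCOR3 libraries more than RCOR1 replicate 1. The lower of its indices with RCOR3 minus that with RCOR1 replicate 1 was 0.0985 with all peaks, 0.0258 with equal numbers of top peaks (SE 0.0488 over chromosomes), 0.0477 at 500 bp, −0.0311 with both, and 0.106 without uninduced peaks, so its sign depends on the setting. Background also seen in the uninduced FLAG libraries is argued against as the whole cause by the 0.106 (SE 0.00706). Background particular to the RCOR1 and RCOR3 antibodies stays open, because only peaks with an uninduced FLAG peak were left out. List length and width could account for RCOR3 replicate 2 (−0.0311, SE 0.00633) but not for RCOR3 replicate 1 (0.0384, SE 0.00441). A wrong label cannot be told apart, because the index exceeded that of the RCOR3 libraries with each other by 0.0706 with an SE of 0.0360. The peak names within this list name RCOR1, as its label does, which shows no mix-up after peak calling and leaves an earlier one open. A real overlap of RCOR1 and RCOR3 sites was not tested and stays open.

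Uninduced FLAG peaks were frequent in RCOR2-high regions. Gene ends are argued against by a difference of at least 42.5 points within both classes of position, and region width by 46.9 points at equal width. Leaking expression of tagged RCOR2 may contribute, since uninduced peaks were in 81.8% of the 1666 RCOR2-high regions with the highest induced scores and 46.3% of the 1666 with the lowest (35.5 points). RCOR3 replicate 2 rose by 30.6 points between the same sets (replicate 1 by 3.72), so this does not separate a leak from background at strongly enriched sites. No biological explanation was tested for this pattern.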

How the results depend on the processing

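Leaving out replicates of the protein test, the crossed numbers, the top-peak gene lists, the lists without uninduced peaks in the regions of each protein, and the RCOR2-high and RCOR2-low comparisons restricted to regions without uninduced peaks (for LSD1, RCOR1 and RCOR3) or to regions holding RCOR2 were chosen after seeing the data. Except where a setting's construction shows it, the cause was not tested. Co-occupancy of RCOR2 with each protein, and the LSD1 and gene-end differences between RCOR2-high and RCOR2-low regions, kept direction and call under every alternative run. Of the values for main comparisons, 25 moved, 7 weakened, 2 strengthened and 4 reversed, and the others held. Of the values for single lists 319 held, 51 lost their call and 20 changed sign. Some of these sign changes come from the continuity correction alone, in lists whose members were all bound. Motifs, GC-matched windows and the CpG-rich background were not run.

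Replicate numbers do not establish pairs, since the mean index of libraries of different proteins was 0.142 for equal and 0.137 for different numbers. With the replicate block, the difference in similarity was 0.188 and lost its call (exact p = 0.0833, smallest possible 0.0417). Leaving out replicates gave 0.128 to 0.252.

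The uninduced share of RCOR2 regions was 6.47% with 50% reciprocal overlap, 20.1% for peaks above the median score, 10.1% with the replicate block, 11.8% with numbers crossed, and 15.2 to 18.5% without single replicates. The share of LSD1 regions with RCOR2 was 3.15% with top peaks, 9.62% with 50% overlap and 15.2 to 28.0% without single replicates. That with RCOR3 was 20.4% with 50% overlap and 21.3 to 44.8% without replicates, and that with RCOR1 31.2 to 83.5%. The F of gene-end shares was 28.6 with top peaks and 4.30 to 15.03 without replicates.

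The RCOR1 difference between RCOR2-high and RCOR2-low regions was −0.805 to 38.2 points without single replicates. The RCOR3 difference was −1.59 points at 500 bp, −6.83 without uninduced peaks, −6.13 in regions holding RCOR2, 2.67 away from gene ends and 1.34 to 22.9 without replicates.

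List calls numbered 7 in place of 26 among genes bound by at least 1 protein and 11 when the regions of each protein were taken without uninduced peaks. Among bound genes the RCOR2 log2 odds ratio was −0.043 for MYC targets, −0.043 for splicing factors and −1.36 for ribosomal proteins. It was −0.091 for cell cycle, −1.59 for oxidative phosphorylation and −0.69 for p53 targets. Nearly all these genes are bound, which leaves few unbound. For MYC targets, splicing factors, cell cycle and p53 targets all members were bound, so the negative sign comes from the continuity correction. The 3 lists bound less often kept 3 to 5 members there, too few for a call. Without uninduced peaks it was −0.12, −0.70 and −0.023 for the first 3, −0.47 for oxidative phosphorylation and −0.21 for p53 targets, and for RCOR3 −0.018 for splicing factors. With top peaks it was −0.16 for ribosomal proteins and −1.14 for HOX genes, and by nearest gene end −0.19 for oxidative phosphorylation. RCOR2 against the other proteins gave 5 calls with top peaks and 0 to 1 without replicates, and RCOR2-high against RCOR2-low 4 by nearest gene end. The number of peaks per library, from 10253 to 75643, limits what sharing can be seen.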

Other observations

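The counts of RNA genes and the MYCN surroundings were looked at after the main results were seen and carry no test. Induced RCOR2 peaks lay within 100 bp of 41.3% ± 0.319 of 443 tRNA genes, against 16.3% ± 8.62 in the uninduced control (SD, n = 2 each). The shares were 46.1% and 20.1% ± 15.6 for 154 snRNA genes and 13.2% ± 0.666 and 1.99% ± 0.444 for 1911 miRNA genes (SD, n = 2). For 49 rRNA genes they were 66.3% ± 1.44 and 57.1% ± 5.77 (SD, n = 2). An excess over the control was also found at protein-coding genes (79.5% ± 0.460 against 21.3% ± 4.95) and lncRNA genes (35.9% ± 0.482 against 6.49% ± 0.692, SD, n = 2). The induced libraries had 5.37 times the mean peak number of the control, and the gene classes were not matched on length. These shares therefore cannot show whether the excess was particular to any class. LSD1 peaks lay at 20.9% ± 7.82 of the tRNA genes, 0.445% ± 0.0370 of the miRNA genes and 18.4% ± 2.07 of protein-coding genes (SD, n = 2).

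The 2 Mb either side of MYCN, amplified in these cells, hold 0.137% of the usable sequence. They held 1.21% ± 1.03 of RCOR1, 1.00% ± 0.362 of induced RCOR2, 2.24% ± 1.81 of RCOR3, 2.20% ± 0.366 of LSD1 and 1.88% ± 1.13 of uninduced FLAG peaks (SD, n = 2 each). The excess was present in the uninduced control too (13.8 times the share of sequence).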
